A study of Mus musculus with 60 samples.

How the data were processed

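Gene expression was measured by RNA-seq of polyadenylated RNA from mouse embryonic stem cells in 60 libraries, with 3 biological replicates in each of 20 groups. The groups combine 4 lines (1A wild type, V19 wild type, 1A Ezh2 knockout and 1A Eed knockout) with 5 times in 2i (0, 12, 24, 48 and 96 h). Per the labels' protocols, cells grew in serum with LIF, and CHIR99021 at 3 µM and PD0325901 at 1 µM were renewed daily. Libraries were made with a NEBNext Ultra II kit and sequenced in 2 runs of single reads that were merged per library. Every library was assigned to its group from its label, and 0 columns of the deposited tables stayed unmatched.

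The deposited table of raw counts holds whole-number read counts per gene, made with STAR 2.7.10b and featureCounts 2.0.3 per the submitters' processing notes, which also name MultiQC 1.14, DESeq2 and the builds GRCm39 and mm39. The authors also deposited a score per gene and library, namely counts normalized by removal of unwanted variation (RUV) and rounded to whole numbers, as the name of the table says. Checked on the values, its genes are those with more than 5 raw counts in at least 2 libraries. The RUV settings are not stated, so the factors removed are unknown. A deposited table of transformed counts rises with the raw counts of the same library and was not used here. Coordinates and exon lengths are those listed with the raw counts, and no reference annotation of another build was used.

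Library totals were 2561169 to 11065948 assigned reads (median 6055990), with 17316 to 23126 genes having a count. Mitochondrial genes took 0.609 to 2.17% of the counts and the 10 most abundant genes 4.01 to 5.63%. Of 50559 genes, 15098 had no count in any library. Genes passing edgeR's filterByExpr by group, with a minimum count of 10 and a minimum total of 15, were tested, which left 15083.

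Differences were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested (edgeR 4.0.16, R 4.3.3), with TMM factors, all 60 libraries in 1 model of 20 groups and 40 residual degrees of freedom. A gene was called at an adjusted p under 0.05, and calls of at least 2-fold are counted beside. In all, 16 comparisons were made: the 96 h response of each line with 3 earlier times of 1A wild type, the knockouts and V19 against 1A wild type, the knockouts against each other at 0 h, and 3 differences of the 96 h response (interaction terms). Differences of response between lines at 12, 24 and 48 h were not tested. Adjusted p-values without another name come from this test for single genes.

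A set of 28 gene lists, written before the data were examined, was tested with camera (limma 3.58.1) at its preset correlation of 0.01, and again with an estimated correlation. List p-values were adjusted over all lists and comparisons by the Benjamini-Hochberg method, and the smallest raw p written is 1e-15. Counts of list members use calls over all genes, with calls adjusted over the members alone beside them. A gene without a count in 1 group was also set at a bound of 3 counts over the group. Levels are CPM with TMM factors, and log2 CPM uses a prior count of 2.

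Genes named in the text follow a rule written before the data were examined. It takes Ezh2, Eed and Suz12, up to 6 genes per direction with the largest change, and up to 4 called members of each list with the smallest adjusted p. The genes with the largest change also need an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between replicates, a last condition not set for interactions. Predicted genes, pseudogenes and RIKEN symbols are left out of them. Other genes, used for levels or patterns of the closing observations, were chosen after their values were seen. Values of 2 genes are not reported here.

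The steps were tested on simulated counts with 200 changed genes drawn from the real means and library sizes. For the 96 h response of 1A wild type, 58.2% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 92.4% of those changed 4-fold were recovered among 14232 genes, with 7 false calls of 156. For Eed knockout against 1A wild type at 0 h these shares were 56.7, 74.6 and 90.9% among 14244 genes, with 11 false calls of 159. For the difference of the Eed response they were 23.9, 58.2 and 83.3% among 14244 genes, with 12 false calls of 122.

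Replicate numbers are shared between groups in the labels, which do not say that a number marks a shared day. All 60 pairs of libraries within a group were checked for duplicates, and their chi-square per degree of freedom was 1.13 to 25.6 with a median of 2.59. Alternatives were RLE size factors, no filter, a filter at a mean of 1 CPM, a replicate block, DESeq2 1.42.0, the groups compared alone, the RUV-normalized score with limma-trend on log2 values with a pseudocount of 1, and leaving out each library compared. An alternative chosen after seeing the data left out V19 at 48 h, both knockouts at 12 h and replicate 1 of 1A wild type at 24 h, whose replicates lay furthest from their group means.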

Results

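Polyadenylated RNA was sequenced from mouse embryonic stem cells grown in serum with LIF and then exposed to 2i, the pair of the GSK3 inhibitor CHIR99021 (3 µM) and the MEK inhibitor PD0325901 (1 µM). 4 lines were followed: the wild-type lines 1A and V19, and derivatives of 1A without Ezh2 or without Eed. Ezh2 is the main methyltransferase of Polycomb repressive complex 2 (PRC2), which trimethylates histone H3 at lysine 27, and Eed is a core subunit that the complex needs for this activity. Each line was collected at 0, 12, 24, 48 and 96 h with 3 biological replicates, which gave 20 groups and 60 libraries. Library totals ranged from 2561169 to 11065948 assigned reads with a median of 6055990, and 15083 of 50559 genes were tested. Changes are given as log2 fold changes ± standard error with 3 libraries per group, and levels as CPM ± SD (n = 3).

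The targeted genes were read first in every library. Ezh2 (chromosome 6, 47507208 to 47572309, GRCm39) was at 14.5 to 19.9 CPM in the 15 Ezh2 knockout libraries and at 194 to 277.7 CPM in the 15 libraries of 1A wild type. Eed (chromosome 7, 89603862 to 89630184) was at 15.3 to 28.2 CPM in the 15 Eed knockout libraries and at 246.1 to 393.4 CPM in 1A wild type. No library of either knockout overlapped the wild-type range of its targeted gene. Suz12 (chromosome 11, 79883932 to 79924949), the remaining core subunit, was at 184.1 to 350.8 CPM in 1A wild type, 247.6 to 328.7 CPM in Ezh2 knockout and 212.4 to 281.9 CPM in Eed knockout. The first principal component of all libraries held 39.5% of the variance and the second 17.5%.

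The first question was how wild-type 1A cells changed in 2i. At 12 h, targets of the ERK pathway and genes of the formative and primed state had fallen together. Among 22 ERK targets 20 fell and 2 rose, with a median of -1.57, and the feedback regulators Spry4 (-4.76 ± 0.14) and Dusp6 (-4.19 ± 0.12) fell with the transcription factors Myc (-4.0 ± 0.12) and Egr1 (-5.83 ± 0.24). Dusp6 went from 189.8 ± 16.2 to 10.3 ± 0.499 CPM. Of 20 formative and primed genes 16 fell and 2 rose (median -2.05), among them Otx2 (-5.06 ± 0.28) and Pou3f1 (-4.06 ± 0.16), which are transcription factors of the primed state. The de novo DNA methyltransferases Dnmt3a (-3.24 ± 0.11) and Dnmt3b (-2.21 ± 0.11) and their cofactor Dnmt3l (-1.67 ± 0.12) fell too. Naive pluripotency genes went the other way, with 10 of 20 higher and 4 lower (median 0.47), led by Nanog (1.72 ± 0.09), Tbx3 (1.75 ± 0.11) and Prdm14 (1.76 ± 0.12), while Gbx2 fell by 1.58. All 9 core pluripotency genes fell, Utf1 at -2.95 ± 0.10.

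Adjusted p-values of these lists at 12 h were 5.6e-14 for ERK targets, 1.3e-12 for formative and primed genes, 8.9e-04 for naive genes and 3.3e-09 for core pluripotency genes. Adjusted over the list alone, the counts were the same except for naive genes, with 12 higher and 4 lower. In all, 6148 genes were called at 12 h, 3014 higher and 3134 lower, of which 772 and 952 changed at least 2-fold. The largest rises under the rule for named genes were those of Trpm1 (5.52 ± 0.37), S100a13 (4.77 ± 0.32) and Ap3b2 (4.38 ± 0.14). The list of Wnt targets did not move one way, with 6 of 18 members higher and 5 lower (7 and 5 adjusted over the list alone, adjusted p = 0.76). Cdx1 rose (3.60 ± 0.20) and Bmp4 (-4.49 ± 0.18) and Lef1 (-3.38 ± 0.19) fell.

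At 24 and 48 h naive genes had moved further from 0 h. The medians of the other lists at these times were -1.66 and -1.57 for ERK targets, -1.71 and -2.05 for formative and primed genes, and -0.64 and -0.79 for core pluripotency genes. Naive genes were higher in 14 of 20 cases at both times, with medians of 1.08 and 1.21, and 5 and 4 members were lower (14 against 5 at both times adjusted over the list alone). Tbx3 was at 2.92 ± 0.11 and 3.36 ± 0.11, and Prdm14 at 2.28 ± 0.12 and 3.25 ± 0.11. Spry4 was at -4.85 ± 0.14 at 24 h and -6.82 ± 0.18 at 48 h. Ribosome biogenesis genes and Myc targets fell in 22 of 30 cases at 24 h and in 21 of 30 at 48 h, with medians of -0.44 and -0.34, and these counts were the same adjusted over the list alone (adjusted p = 1.7e-07 and 9.4e-07). The cell cycle inhibitor Cdkn1a rose by 1.78 ± 0.08 and 2.32 ± 0.08. Trophoblast genes were higher in 10 of 16 cases and lower in 3 at 48 h (also 10 and 3 adjusted over the list alone), with Krt8 at 1.55 ± 0.12 and Krt18 at 1.64 ± 0.12, at an adjusted p of 0.0067 that became adjusted p = 0.053 with an estimated correlation. The list's call also ended in the authors' RUV-normalized values, where its median was 0.88. The totals were 7002 genes at 24 h (3624 higher, 3378 lower) and 7989 at 48 h (4043 higher, 3946 lower). Replicate 1 at 24 h stood apart from its group, with a root mean square deviation of 0.262 log2 units against a median of 0.121 over all libraries, and without it 7352 genes were called at 24 h.

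At 96 h, 7324 genes differed from 0 h in 1A wild type, 3786 higher and 3538 lower, of which 1483 and 1388 changed at least 2-fold. Formative and primed genes stayed low, with 16 of 20 lower and 1 higher (median -1.87, adjusted p = 1.2e-11), and Dnmt3a went from 696 ± 18.3 to 54.9 ± 5.38 CPM (-3.67 ± 0.11). ERK targets were lower in 15 of 22 cases and higher in 3 (median -1.13, adjusted p = 2.1e-07, 17 lower adjusted over the list alone), with Egr1 at -7.79 ± 0.31, Myc at -3.27 ± 0.11 and Dusp6 at -3.25 ± 0.11. Naive genes were higher in 14 of 20 cases and lower in 4 (median 0.70, adjusted p = 2.4e-05), with Tbx3 at 3.36 ± 0.11, Prdm14 at 3.12 ± 0.11, Nanog at 2.08 ± 0.09 and Tcl1 at 1.94 ± 0.11. Core pluripotency genes fell in 7 of 9 cases (median -0.48, adjusted p = 1.2e-04), led by Utf1 (-2.06 ± 0.09) and Lin28a (-1.70 ± 0.09). Adjusted over the list alone, the counts of these formative, naive and core lists were the same.

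Further groups changed at 96 h. Ribosome biogenesis genes and Myc targets fell in 24 of 30 cases with 1 higher (the same counts adjusted over the list alone, median -0.40, adjusted p = 3e-07), among them the polyamine enzyme Srm (-1.15 ± 0.08). Hox genes, which pattern the body axis, rose in 14 of 29 cases and fell in none called (also 14 adjusted over the list alone, adjusted p = 0.0023), with Hoxc13 at 3.61 ± 0.29. Their fitted median of 2.69 was 1.06 when the 8 members without a count in 1 group were set at their bound of 3 counts over the group, and 0.64 in the authors' RUV-normalized values. Cholesterol biosynthesis genes rose in 11 of 24 cases and fell in 2 (11 and 3 adjusted over the list alone, adjusted p = 0.039, but adjusted p = 0.12 with an estimated correlation). Imprinted genes fell in 20 of 41 cases and rose in 7 (the same counts adjusted over the list alone, adjusted p = 0.0024, and adjusted p = 0.052 with an estimated correlation), with Plagl1 at 4.86 ± 0.20 and Sfmbt2 at -2.48 ± 0.16. Among the largest single changes, Trpm1 rose (6.43 ± 0.33) and Esrp1, a splicing regulator of epithelial cells, fell (-5.99 ± 0.14). Ccdc194 had 203 counts over the 3 libraries at 0 h and 0 at 96 h, at least 68.3-fold lower.

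**Figure D1:**
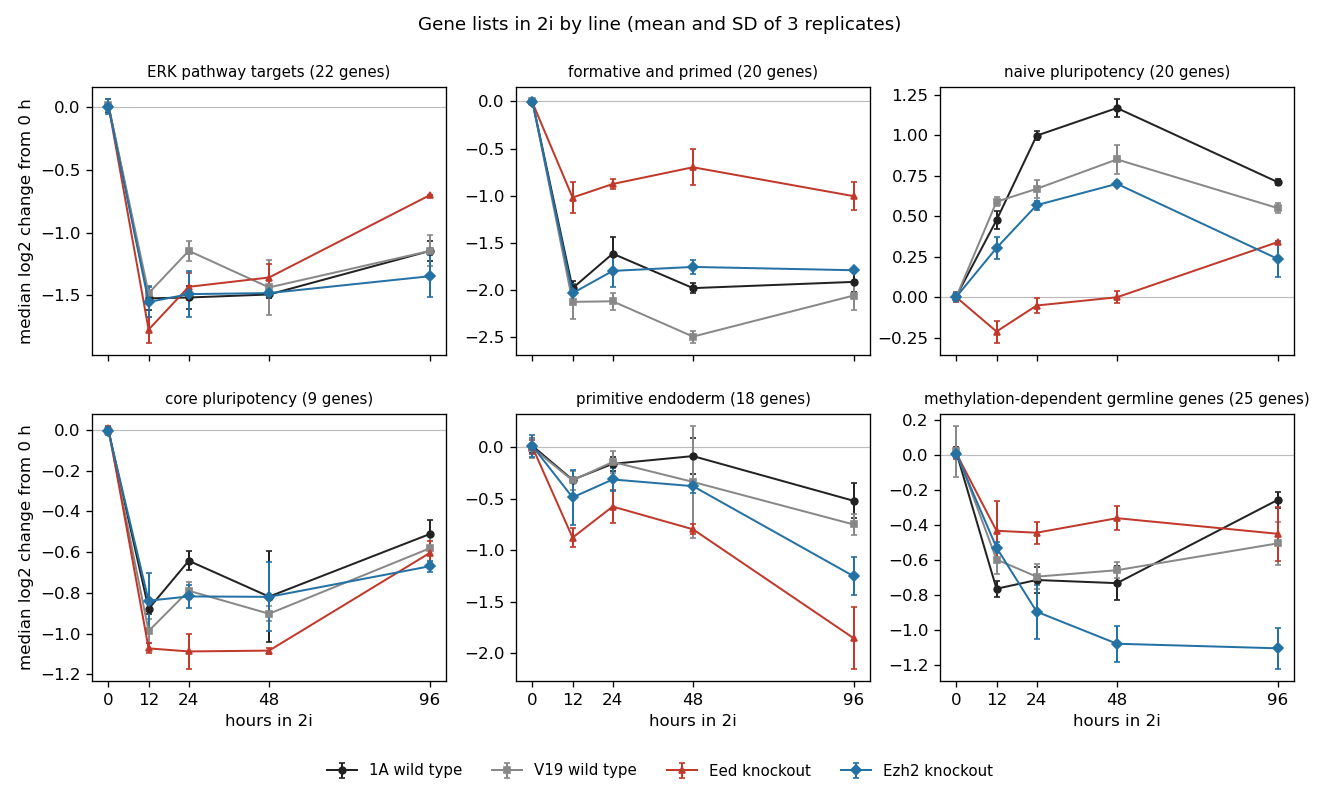
Median log2 change from 0 h (vertical axis) over hours in 2i (horizontal axis) for 6 gene lists in the 4 lines. Points are means over 3 replicates and bars are SD, which at later times leaves out the variation of the 0 h libraries. The formative and primed list lies at -1.92 in 1A wild type and at -1.01 in Eed knockout at 96 h.

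The V19 line gave an independent wild-type response. At 96 h it had 7158 called genes, 3738 higher and 3420 lower, of which 1592 and 1209 changed at least 2-fold. Formative and primed genes fell in 16 of 20 cases and rose in 2 (median -2.07), ERK targets fell in 16 of 22 and rose in 2 (median -1.25), and naive genes rose in 13 of 20 and fell in 5 (median 0.56), with the same counts adjusted over the list alone and adjusted p-values of 2e-11, 4e-08 and 0.003. Dnmt3a (-3.56 ± 0.11), Egr1 (-7.03 ± 0.30) and Esrp1 (-5.63 ± 0.15) fell, and Nanog rose (1.68 ± 0.09). Across the 15083 genes the log2 changes of V19 and 1A correlated with r = 0.818 (SD 0.0076 over the 3 V19 replicates at 96 h), where genes are not independent replicates, and with r = 0.437 over all genes with a count when none was filtered out. The SD of r leaves out the variation of the V19 libraries at 0 h and of all 1A libraries. Of 5439 genes called in both lines, 5421 changed in the same direction (99.7%).

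The next question was how the knockouts differed before 2i. In the labels each knockout is a single line, and its replicates repeat that line. Loss of the gene therefore cannot be told apart from other traits of the line, and the words without Eed and without Ezh2 name these lines. Without Eed, 7488 genes differed from 1A wild type at 0 h, 3980 higher and 3508 lower, and 2102 and 723 of them by at least 2-fold. Developmental genes were among the rises. Of 71 bivalent developmental regulators, which carry active and repressive histone marks in stem cells, 53 were higher and 7 lower (55 and 7 adjusted over the list alone, median 2.57, or 2.55 with 2 members at their bound, adjusted p = 4.7e-12). All 29 Hox genes tested were higher, and their median of 4.0 was 3.55 with 7 members at their bound (adjusted p = 3.7e-12). All 18 primitive endoderm genes were higher (median 3.76), including Sox17 (5.70 ± 0.25), Gata6 (4.16 ± 0.19) and Sparc, which went from 321 ± 9.77 to 1409 ± 70.2 CPM. Trophoblast genes were higher in 15 of 16 cases and lower in 1, with a median of 2.81 in raw counts but of -0.25 in the authors' RUV-normalized values. Among them, Hand1 was at 6.02 ± 0.18 in raw counts and 0.35 in the RUV-normalized values, and Krt8 at 2.71 ± 0.12 and -0.58. By those values the bivalent, Hox and primitive endoderm medians were smaller, at 0.50, 1.09 and 1.36, and Sox17, Gata6 and Sparc were at 2.48, 1.21 and 0.88. The adjusted p-values of the primitive endoderm and trophoblast lists were 5.6e-14 and 9.5e-14, and the Hox, primitive endoderm and trophoblast counts were the same adjusted over the list alone. Fibroblast and feeder markers, which mark another cell type, were higher in 9 of 15 cases and lower in 3 (the same adjusted over the list alone, median 1.23, or 1.03 with 1 member at its bound), but the list was not called (adjusted p = 0.14), while it was called without a filter (median 1.23, adjusted p = 0.016) and had a median of -0.26, not called, in the RUV-normalized values.

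Other groups also differed without Eed at 0 h. Methylation-dependent germline genes were higher in 20 of 25 cases and lower in none called (median 1.37, adjusted p = 1.5e-08), with Sohlh2 at 2.80 ± 0.17 and Mael at 2.11 ± 0.13. All 13 genes of the 2-cell-like list were higher, with a median of 5.59 that became 5.13 with 4 members at their bound (adjusted p = 1.9e-10), but the Zscan4 and Usp17l members of this list are near-identical copies between which reads can be split. The same list was also higher in wild-type V19 against these 1A libraries, by a fitted median of 1.97. The imprinted RNA H19 (chromosome 7, 142129267 to 142131883) went from 16 ± 1.87 to 1805 ± 118 CPM (6.83 ± 0.16, but -0.16 in the RUV-normalized values) and its neighbour Igf2 rose by 4.65 ± 0.14. The neighbouring imprinted RNAs Meg3 (-3.05 ± 0.14) and Rian (-2.71 ± 0.13) were lower. All 9 core pluripotency genes were lower (median -0.66, adjusted p = 3.3e-06), with Sox2 at -0.89, while in the RUV-normalized values the list's median and Sox2 were both at 0.13. Ribosome biogenesis genes and Myc targets were lower in 28 of 30 cases (median -0.42, adjusted p = 6.5e-10), a call that ended at a median of -0.00139 in those values. The counts of these germline, 2-cell-like, core and ribosome lists were the same adjusted over the list alone. In the RUV-normalized values the germline and 2-cell-like medians were 0.44 and 1.48, and Sohlh2, Mael, Igf2, Meg3 and Rian were at 1.10, 0.87, 0.62, -1.61 and -1.29. By these values 3005 genes were called at 0 h, and Eed itself was at -0.61 against 1A wild type, where the raw counts gave -3.94 ± 0.12.

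Without Ezh2, 3433 genes differed from 1A wild type at 0 h, 1796 higher and 1637 lower, of which 546 and 579 changed at least 2-fold. Methylation-dependent germline genes were higher in 18 of 25 cases and lower in none called (the same adjusted over the list alone, median 1.07, adjusted p = 5.6e-14), with Fkbp6 at 3.21 ± 0.15 and Mael at 2.07 ± 0.13. Naive genes were higher in 11 of 20 cases and lower in 1 (14 and 1 adjusted over the list alone, median 0.43, adjusted p = 1.7e-09), with Tbx3 at 2.78 ± 0.11, Prdm14 at 1.96 ± 0.12 and Nanog at 1.16 ± 0.09. Primitive endoderm genes were higher in 14 of 18 cases (15 adjusted over the list alone, median 1.14, adjusted p = 2.4e-07), and bivalent regulators in 24 of 71 with 5 lower (26 and 6 adjusted over the list alone, median 0.48, or 0.78 with the stricter filter, adjusted p = 4e-04). Of 29 Hox genes 9 were higher (11 adjusted over the list alone, adjusted p = 1.6e-04), and their median of 1.77 was 1.23 with 7 members at their bound and 0.92 in the RUV-normalized values.

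Imprinted genes fell in Ezh2 knockout at 0 h, with 21 of 41 lower and 3 higher (22 and 3 adjusted over the list alone, median -0.51, adjusted p = 2e-11). Sfmbt2 (chromosome 2, 10375251 to 10600064), itself a Polycomb-group gene, went from 151 ± 7.69 to 10.5 ± 1.55 CPM (-3.83 ± 0.17), and Peg3 (-1.61 ± 0.13) and Smoc1 (-1.34 ± 0.10) fell. The gluconeogenic enzyme gene Fbp2 rose by 3.87 ± 0.23 and Meis2, a homeobox gene, by 3.05 ± 0.16. Formative and primed genes were lower in 10 of 20 cases and higher in 6 (the same adjusted over the list alone), with an adjusted p of 0.029 and adjusted p = 0.058 with an estimated correlation.

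The knockouts shared part of their calls at 0 h. Of the 15083 genes, 1141 were higher in both and 926 lower in both, while independent lists of the same sizes would share 474 and 381, and 401 genes went in opposite directions. H19, at 1805 ± 118 CPM without Eed by raw counts, was lower without Ezh2 (-2.30 ± 0.21), at 3.12 ± 1.52 CPM. In 20 simulations of unchanged groups against the shared controls, no gene was called by edgeR in both comparisons, which follows from simulating no change. On average 121 simulated genes passed an unadjusted p of 0.05 in the same direction in both, against 2887 observed. In the simulations 4.26 and 4.22% of genes passed that p for Eed and Ezh2 knockout, against 54.8 and 32.6% observed. These counts therefore cannot show how much of the overlap comes from the shared controls. The correlation of the log2 changes was 0.494 observed and 0.542 simulated, and the covariance 0.399 observed and 0.0796 simulated, a difference of 0.320. The controls were redrawn too, so the simulated covariance, 0.0725 to 0.0868 over the 20 simulations, is what chance values of shared controls give. A trait common to all 3 control libraries was not simulated. These libraries cannot be split into 2 parts of 2, so part of the difference may still come from such a trait.

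Tested directly against each other at 0 h, Eed and Ezh2 knockout differed in 6832 genes, 3564 higher and 3268 lower without Eed, and 1949 and 448 of them by at least 2-fold. Trophoblast genes were higher without Eed in 15 of 16 cases (median 2.69), primitive endoderm genes in 18 of 18 (median 2.47) and bivalent regulators in 50 of 71 with 7 lower (51 and 7 adjusted over the list alone, median 1.75), at adjusted p-values of 5.6e-14, 5.6e-14 and 5.7e-09. In the authors' RUV-normalized values the trophoblast and bivalent medians were both at 0.16, neither list was called and the trophoblast test pointed the other way. By those values the primitive endoderm median was 0.57. H19 was 9.13 ± 0.18 higher (2.81 in the RUV-normalized values) and Krt8 3.58 ± 0.12 (0.53), while Hand1 was 4.41 ± 0.15 higher in raw counts and at -0.81 in the RUV-normalized values. Naive genes were lower without Eed in 14 of 20 cases and higher in 2 (15 and 3 adjusted over the list alone, median -0.44, adjusted p = 1.6e-04), with a median of 7.08e-06 in the RUV-normalized values. The trophoblast and primitive endoderm counts were the same adjusted over the list alone. Fibroblast and feeder markers, listed as signs of another cell type, were higher without Eed in 10 of 15 cases (11 adjusted over the list alone, adjusted p = 0.0018), and their median of 1.86 was 1.64 with 1 member at its bound, 1.22 with the stricter filter and 0.49, not called, in the RUV-normalized values, while Col1a1 stood at 1.35 ± 0.537 CPM without Eed, 1.28 ± 0.510 CPM without Ezh2 and 3.57 ± 0.692 CPM in 1A wild type, and Col1a2 at 2.71 ± 0.481, 0.360 ± 0.138 and 1.06 ± 0.662 CPM (2.89 ± 0.51 higher than without Ezh2 by raw counts, and 0.90, not called, by the RUV-normalized values). By those values the comparison had 1737 calls, and Eed itself was at -1.09 against Ezh2 knockout where raw counts gave -4.18 ± 0.12.

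At 96 h in 2i the gap between Eed knockout and 1A wild type held 8337 genes, 4656 higher and 3681 lower, of which 2644 and 706 differed at least 2-fold. Trophoblast genes were higher in 16 of 16 cases by raw counts (median 2.94, adjusted p = 5.6e-14) but at a median of -0.59 in the authors' RUV-normalized values. Krt7 was at 3.89 ± 0.15 by raw counts and -1.16 by those values, and Rhox9, which has close copies on the X chromosome, at 4.69 ± 0.16 and -0.72. Isg15, which encodes an interferon-induced ubiquitin-like protein, was at 0.0531 ± 0.0919 CPM in 1A wild type and 18.5 ± 1.08 CPM in Eed knockout. Bivalent regulators were higher in 59 of 71 cases and lower in 4 (61 and 4 adjusted over the list alone, median 2.32, adjusted p = 1.6e-11), with a median of 0.31, not called, by the RUV-normalized values. Imprinted genes were higher in 25 of 41 cases and lower in 9 (median 0.94, adjusted p = 4e-04, and 0.24, not called, by those values), with Cdkn1c, an inhibitor of the cell cycle, at 4.93 ± 0.13 by raw counts and 1.13 by the RUV-normalized values. Naive genes were lower in 9 of 20 cases and higher in 2 (median -0.21, adjusted p = 0.0081), with Nr0b1 at -1.89, while by the RUV-normalized values their median was 0.31 and Nr0b1 was at 0.088. The trophoblast, imprinted and naive counts were the same adjusted over the list alone. Fibroblast and feeder markers were higher in 10 of 15 cases and lower in 2 (10 and 3 adjusted over the list alone, adjusted p = 0.045, but adjusted p = 0.052 with an estimated correlation), a call that ended with the stricter filter (median 0.91) and turned with the RUV-normalized values (-0.089), and 3 of 7 mitochondrial genes were higher (2 adjusted over the list alone, adjusted p = 0.39). By the RUV-normalized values 3486 genes were called, and Eed itself was at -0.18 where raw counts gave -4.09 ± 0.12.

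Between Ezh2 knockout and 1A wild type 1992 genes differed at 96 h, 989 higher and 1003 lower, and 156 and 264 of them by at least 2-fold. Hox genes were higher in 13 of 29 cases and lower in 1 (17 and 1 adjusted over the list alone, adjusted p = 2e-11), with Hoxc10 at 2.77 ± 0.30 and a median of 1.42 that became 0.99 with 2 members at their bound and 0.74 with the stricter filter. Cholesterol biosynthesis genes were higher in 14 of 24 cases (17 adjusted over the list alone, median 0.38, adjusted p = 5.5e-09), with Sqle at 0.60 ± 0.07, and Wnt targets in 7 of 18 (the same adjusted over the list alone, median 0.41, adjusted p = 6.6e-05), with Ccnd1 at 0.76 ± 0.09. Otx2 was 3.08 ± 0.29 higher and Meis2 1.86 ± 0.12 higher. Fibroblast and feeder markers were lower in 5 of 15 cases and higher in 1 (6 and 1 adjusted over the list alone, adjusted p = 7.8e-04), among them the smooth muscle actin Acta2 (-2.87 ± 0.17), and their median of -1.59 was -1.17 with 2 members at their bound and -0.90 with the stricter filter. Without replicate 1 of 1A wild type at 96 h 1180 genes were called, without replicate 3 of Ezh2 knockout at 96 h 1325, and without 3 other groups and 1 library that stood apart 2989. With the authors' RUV-normalized values the split was 612 higher and 1090 lower.

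V19 and 1A, the wild-type lines, differed in 1590 genes at 0 h, 756 higher and 834 lower in V19, and 105 and 234 of them by at least 2-fold. Of these, 363 lay on chromosome 8 (22.8%), and 355 of them were higher in V19. The median change over the 812 tested genes of chromosome 8 was 0.40, and 0.16 over all 1809 with a count when none was filtered out, while those of the other autosomes lay between -0.05 and 0.05. At the later times the median over 542 more highly expressed genes of this chromosome stayed between 0.36 ± 0.0044 (SD, n = 3) at 96 h and 0.41 ± 0.019 at 0 h. In the same comparison at 0 h the autosome medians were -0.09 to 0.09 for Eed knockout and -0.02 to 0.04 for Ezh2 knockout. The Y-linked genes Uty (-3.08 ± 0.17), Eif2s3y (-2.92 ± 0.13) and Ddx3y (-2.88 ± 0.17) were lower in V19, and the X-linked ubiquitin ligase gene Mid1 was higher (3.56 ± 0.27).

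**Figure D2:**
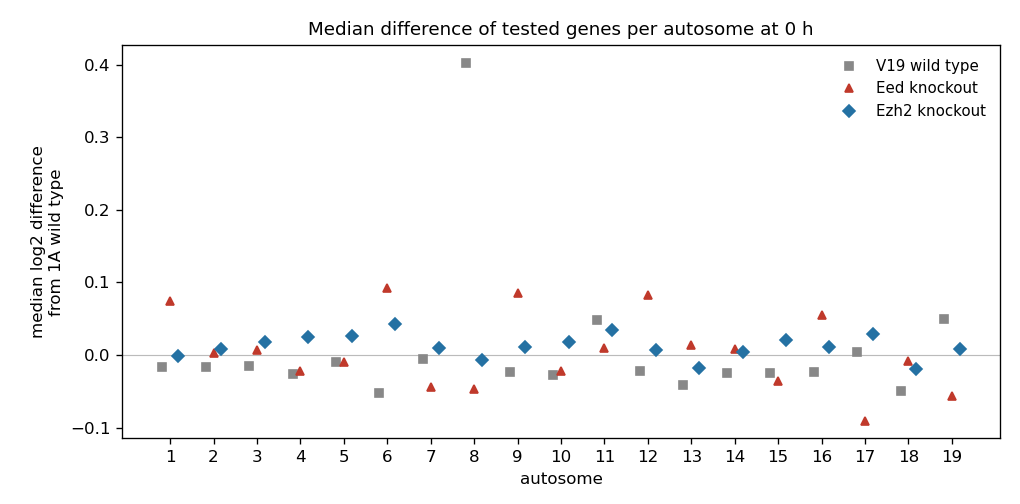
Median log2 difference from 1A wild type at 0 h (vertical axis) of the tested genes on each autosome (horizontal axis) for V19, Eed knockout and Ezh2 knockout. Chromosome 8 in V19 lies at 0.40 and every other point lies between -0.09 and 0.09.

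Trophoblast genes were lower in V19 than in 1A at 0 h in 6 of 16 cases (7 adjusted over the list alone, median -0.65, or -0.17 in the RUV-normalized values, adjusted p = 1.4e-07), with Krt18 at -1.92 ± 0.13 and Krt8 at -1.66 ± 0.13. Naive genes were higher in 8 of 20 cases and lower in 1 (9 and 1 adjusted over the list alone, median 0.18, adjusted p = 3.2e-08), with Tbx3 at 1.35 ± 0.12. Imprinted genes were lower in 14 of 41 cases and higher in 2 (19 and 2 adjusted over the list alone, median -0.31, adjusted p = 2.7e-06). Methylation-dependent germline genes were higher in 5 of 25 cases and lower in 1 (the same adjusted over the list alone, median 0.285, adjusted p = 0.0014). Primitive endoderm genes were higher in 6 of 18 cases (9, with 1 lower, adjusted over the list alone, median 0.53, adjusted p = 0.0012, but adjusted p = 0.085 with an estimated correlation). Bivalent regulators were higher in 10 of 71 cases and lower in 1 (12 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.038). The 2-cell-like list was higher too, as in Eed knockout, with 2 of 13 members called (3 adjusted over the list alone). Its fitted median was 1.97 (adjusted p = 6.7e-04, and adjusted p = 0.017 with an estimated correlation). The naive, imprinted, germline, primitive endoderm and bivalent lists moved the same way in Ezh2 knockout against the same 1A libraries at 0 h. With only the groups compared in the fit, 2415 genes were called.

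The remaining question was whether the response to 2i itself differed in the knockout lines. In Eed knockout, 5982 genes changed over 96 h, 3513 higher and 2469 lower, of which 1282 and 661 changed at least 2-fold. The excess of rises was smaller with the stricter filter (2915 higher, 2785 lower) and with only the groups compared in the fit (3634 and 3473). ERK targets fell in 14 of 22 cases and rose in 2 (median -0.70, adjusted p = 2e-09), with Dusp6 at -3.54 ± 0.12, and formative and primed genes fell in 13 of 20 and rose in 5 (median -1.10, adjusted p = 2.6e-05). Primitive endoderm genes, which started high in this line, fell in 17 of 18 cases (median -1.97, adjusted p = 5.6e-14), with Gata4 at -2.39 ± 0.14. These 3 lists had the same counts adjusted over the list alone. The alcohol dehydrogenase gene Adh1 went from 0.276 ± 0.0885 to 58.7 ± 6.07 CPM (7.62 ± 0.29, and 4.84 in the RUV-normalized values), and Cubn, an endocytic receptor of the endoderm, from 119 ± 23.9 to 0.751 ± 0.482 CPM (-7.30 ± 0.31).

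In Ezh2 knockout, 6460 genes changed over 96 h, 3343 higher and 3117 lower, of which 1102 and 1193 changed at least 2-fold. More genes were lower than higher with RLE size factors (3043 higher, 3453 lower), with DESeq2 (2861 and 3370) and with the RUV-normalized values (2763 and 3323). ERK targets fell in 16 of 22 cases and rose in 2 (median -1.40, adjusted p = 2.2e-10), and formative and primed genes fell in 15 of 20 and rose in 4 (median -1.80, adjusted p = 6.4e-09). Methylation-dependent germline genes fell in 17 of 25 cases and rose in 3 (18 and 4 adjusted over the list alone, median -1.27, adjusted p = 1.5e-09), with Ddx4 at -3.72 ± 0.13 and Mael at -2.81 ± 0.13. Cholesterol biosynthesis genes rose in 18 of 24 cases (19 adjusted over the list alone, median 0.60, adjusted p = 6.5e-07). The ERK and formative counts were the same adjusted over the list alone. Sp5, a direct Wnt target, rose by 4.30 ± 0.28.

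The difference of the 96 h responses was tested as an interaction. Eed knockout and 1A wild type responded differently in 4115 genes, 2250 with a higher and 1865 with a lower change in the knockout, while the stricter filter gave 2013 and 2128. Formative and primed genes fell less without Eed, with 14 of 20 differences above 0 and 3 below (15 and 3 adjusted over the list alone, median 1.43, adjusted p = 2e-07). Dnmt3a differed by 2.41 ± 0.15 and Pou3f1 by 2.66 ± 0.22. Naive genes differed downward in 11 of 20 cases and upward in 3 (12 and 4 adjusted over the list alone, median -0.52, adjusted p = 1.1e-04), with Tbx3 at -3.00 ± 0.15. Tbx3 was at 30.5 ± 1.71 CPM in 1A wild type and 227 ± 8.45 CPM in Eed knockout at 0 h, and at 312 ± 11.6 and 292 ± 6.4 CPM at 96 h. Primitive endoderm genes differed downward in 12 of 18 cases (the same adjusted over the list alone, median -1.60, adjusted p = 1.5e-09), and imprinted genes upward in 22 of 41 with 3 downward (24 and 3 adjusted over the list alone, median 0.97, adjusted p = 1.4e-07).

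Ezh2 knockout and 1A wild type responded differently in 1837 genes, 818 upward and 1019 downward. Methylation-dependent germline genes differed downward in 16 of 25 cases (median -1.28, adjusted p = 5.6e-14), with Mael at -2.44 ± 0.21, and naive genes in 13 of 20 (median -0.60, adjusted p = 4.3e-10), with Tbx3 at -2.81 ± 0.15, and both counts were the same adjusted over the list alone. Imprinted genes differed upward in 16 of 41 cases and downward in 1 (18 and 1 adjusted over the list alone, median 0.47, adjusted p = 2.1e-07). The germline and naive lists, with Mael and Tbx3, were already higher in Ezh2 knockout than in 1A wild type at 0 h, and the imprinted list was lower. Lefty1, an antagonist of Nodal signalling, differed by 3.36 ± 0.29. V19 and 1A wild type responded differently in 254 genes, 147 upward and 107 downward, and naive genes differed downward in 6 of 20 cases and upward in 1 (8 and 1 adjusted over the list alone, median -0.24, adjusted p = 6.4e-07). Naive genes were also higher in V19 than in 1A wild type at 0 h, with Tbx3 at 77.9 against 30.5 CPM. At 96 h Tbx3 was at 333 against 312 CPM, while Nr0b1 ended lower in V19, at 150.7 against 230.5 CPM. From the interactions alone, a different start and a different response of these lists cannot be told apart. Between V19 and 1A 1030 genes were called with only the groups compared in the fit, and 601 without the 3 groups and 1 library that stood apart. By the authors' RUV-normalized values the split was 158 upward and 182 downward. The log2 differences of this interaction followed exon length with a rank correlation of 0.266, where its 2 parts, the 96 h responses of V19 and of 1A wild type, gave 0.0811 and -0.0626. Trends of similar size were found in the 2i response of 1A wild type at 48 h (-0.260) and 12 h (-0.230) and in V19 against 1A at 0 h (-0.220), and the first component of the deviations of libraries from their groups also followed exon length (correlation of 0.562 in size).

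The 1A lines were also read on genes chosen by their change in V19, in a test whose filter and spread came from all 60 libraries, those of 1A included. The 1592 genes that rose at least 2-fold in V19 at 96 h had a median change of 1.27 ± 0.029 (SD, n = 3) in 1A wild type, 0.71 ± 0.024 in Eed knockout (56.1% of the wild-type value) and 0.93 ± 0.032 in Ezh2 knockout (72.8%). The 1209 genes that fell at least 2-fold in V19 had medians of -1.51 ± 0.051, -0.48 ± 0.0053 (31.6%) and -1.27 ± 0.018 (83.8%). These are changes from the 0 h level of each line itself. Levels of the chosen genes at 0 h were not compared between lines, so a different start and a weaker response cannot be told apart. Each knockout differed from 1A wild type in both sets by more than the spread between replicates at 96 h. The two-sided exact permutation p was 0.1 each, the smallest that 3 against 3 libraries allow. Spread and p leave out the variation of the 0 h libraries, whose mean was subtracted from each later library. The V19 libraries at 48 h stood apart from each other, with replicates 2 and 3 at root mean square deviations of 0.357 and 0.267 log2 units against a median of 0.121 over all libraries, so a choice of genes at 48 h rests on uneven replicates. Over time, the genes that rose at least 2-fold in V19 at 48 h had medians of 0.66, 0.95, 1.22 and 1.04 at 12, 24, 48 and 96 h in 1A wild type, of 0.56, 0.67, 0.74 and 0.68 in Eed knockout, and of 0.81, 1.05, 1.14 and 0.84 in Ezh2 knockout, which lay above 1A wild type at 12 and 24 h. The genes that fell in V19 at 48 h had medians of -0.92, -1.15, -1.42 and -1.25 in 1A wild type, -0.73, -0.61, -0.61 and -0.50 in Eed knockout, and -0.95, -1.10, -1.30 and -1.06 in Ezh2 knockout.

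**Figure D3:**
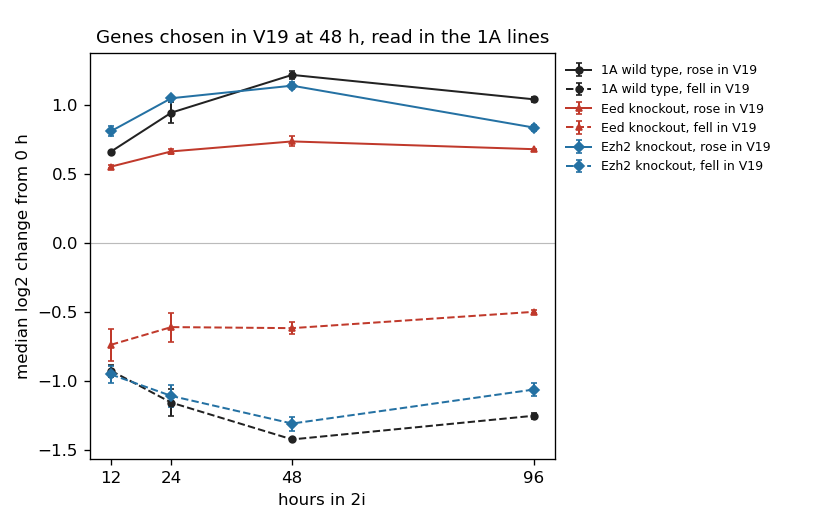
Median log2 change from 0 h (vertical axis) over hours in 2i (horizontal axis) in the 1A lines. The genes read are those that rose or fell at least 2-fold in V19 at 48 h. Points are means and bars are SD over 3 replicates, which leaves out the variation of the 0 h libraries. At 96 h the rising genes lie at 1.04 in 1A wild type, 0.68 in Eed knockout and 0.84 in Ezh2 knockout. Replicates 2 and 3 of V19 at 48 h, on which the choice of genes rests with replicate 1, deviated from their group by 0.357 and 0.267 log2 units.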

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

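The interaction comparisons and the gene lists were set before the data were examined, while the counts over other splits of the libraries were chosen after the results were seen. A tested difference between lines in the 96 h response singled out each result of this part. Eed knockout and 1A wild type differed in 4115 genes. By list, with the adjusted p from an estimated correlation, the Eed differences were formative and primed genes at a median of 1.43 (adjusted p = 3.4e-05), imprinted genes at 0.97 (8.8e-04), naive genes at -0.52 (2.4e-04) and primitive endoderm genes at -1.60 (0.0014). Subunits of Polycomb repressive complex 1 had a median of -0.27 with 6 of 20 lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.017), with Bmi1 at -1.51 ± 0.18 and Cbx8 at -2.90 ± 0.35.

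Ezh2 knockout and 1A wild type differed in 1837 genes. Methylation-dependent germline genes had a median of -1.28 (adjusted p = 5.5e-09), naive genes -0.60 (3.4e-07) and imprinted genes 0.47 (0.0011). Ribosome biogenesis genes differed upward in 8 of 30 cases (9 adjusted over the list alone, median 0.21, adjusted p = 5.3e-05), with Srm at 0.50 ± 0.11, and cholesterol biosynthesis genes in 6 of 24 (9 and 1 downward adjusted over the list alone, median 0.23, adjusted p = 0.024). Formative and primed genes differed upward in 8 of 20 cases and downward in 4 (9 and 4 adjusted over the list alone, median 0.75, adjusted p = 0.0063), with the Nodal antagonists Lefty1 at 3.36 ± 0.29 and Lefty2 at 2.14 ± 0.19. Primitive endoderm genes differed downward in 5 of 18 cases (6 adjusted over the list alone, median -0.78, adjusted p = 0.025), and bivalent regulators in 11 of 71 with 2 upward (the same adjusted over the list alone, median -0.44, or -0.25 in the RUV-normalized values, adjusted p = 0.029). V19 and 1A wild type differed in 254 genes, and naive genes by a median of -0.24 (adjusted p = 8.7e-06). The germline, naive and imprinted lists of Ezh2 knockout and the naive list of V19 already differed from 1A wild type at 0 h.

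Other splits of the 6 libraries of each comparison into groups of 3 were also tested by edgeR on those libraries alone. For the interactions, 0 h and 96 h libraries of the same number were moved together, a choice made to keep differences between lines out of the splits, although the numbers are not taken to pair the libraries, and the 10 splits of an interaction follow from this choice. Each of the 16 results has 10 splits, too few for a share under 0.05, since the smallest possible share is 0.1, and in each 1 split, the real one, gave as many genes. The real counts were 7368, 5541, 7956 and 7648 genes for 1A wild type at 12, 24, 48 and 96 h, and 7580, 7107 and 6610 at 96 h for V19, Eed knockout and Ezh2 knockout. Against 1A wild type they were 7939 and 8776 for Eed knockout at 0 and 96 h, 4765 and 2078 for Ezh2 knockout, and 2415 for V19. Eed against Ezh2 knockout gave 7462, and the interactions of Eed knockout, Ezh2 knockout and V19 gave 5365, 2474 and 1012. The highest of the other splits was 0 genes in every case, with at most 1108 genes at an unadjusted p under 0.05, against at least 3060 in the real splits. A second count without these pairs, added after the first was known, took the 82 splits with as many libraries of each line at 0 h as at 96 h, and its real splits gave 5244, 2369 and 1030 genes for Eed knockout, Ezh2 knockout and V19, against at most 0, 0 and 10 in the other splits. The line stayed in the model of this second count, so its libraries are not fully interchangeable, and it is given beside the first without replacing it. In both counts the other splits put libraries of differing groups together. This raises the spread within groups, so few calls in the other splits were to be expected and do not by themselves measure chance.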

How the results depend on the processing

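Counts of calls were recomputed for the 16 comparisons and the knockout overlap. Of 258 values, 249 stayed within 1.5 times the reported count, and 9 did not. RLE size factors, both other filters, the replicate block and DESeq2 kept all 17 counts within that range. In 10 of 16 comparisons, however, the direction with more calls turned under at least 1 setting, so an excess of one direction is not read from them. They were 1A wild type at all 4 times, V19 and Ezh2 knockout over 96 h, Ezh2 knockout and V19 against 1A wild type at 0 h, and the interactions of Eed knockout and V19. In 0 of 13 comparisons did every pair of same-numbered libraries correlate above 0.1, and the mean correlation of deviations was -5.8e-04 for libraries of the same number and 3.2e-04 for other numbers, so the numbers are not taken to pair the libraries. With the replicate block the counts were, for example, 6125 at 12 h, 7455 for Eed knockout at 0 h and 253 for the V19 interaction.

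The RUV-normalized values gave 3005 calls for Eed knockout against 1A wild type at 0 h (7488 in raw counts), 3486 at 96 h (8337) and 1737 for Eed against Ezh2 knockout (6832). They also lowered the difference at the targeted gene Eed to -0.61, -0.18 and -1.09 in these comparisons, while Ezh2 in Ezh2 knockout stayed at -3.69 (raw counts -3.67). The RUV-normalized values therefore hold less of the difference that defines Eed knockout than raw counts do. Which factors were removed is unknown, and the cause of the moves was not tested. For some lists called in raw counts the direction of the camera test turned. For Eed knockout against 1A wild type their medians were core pluripotency 0.13 and trophoblast -0.25 at 0 h. At 96 h they were fibroblast -0.089, naive 0.31 and trophoblast -0.59. Against Ezh2 knockout they were naive 7.1e-06 and trophoblast 0.16, whose test pointed down. The fibroblast median of Eed knockout against 1A wild type at 0 h, a list called in neither, also changed sign. Named genes called in raw counts that turned were Krt8 (-0.58), H19 (-0.16), Sox2 (0.13) and Cdkn1c (-2.43) at 0 h. At 96 h Krt7 (-1.16), Nr0b1 (0.088) and Rhox9 (-0.72) turned, and against Ezh2 knockout Hand1 (-0.81). The change of Eed over 96 h in Eed knockout was not called in the main fit. It was called at 0.63 by the RUV-normalized values and at -0.34 with the stricter filter. Over all settings, 459 of 480 list results and 1056 of 1083 values of named genes kept their call, and their direction where called. The direction of a list is that of its camera test. Results called in neither setting were counted as kept whatever their direction.

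With only the groups compared in the fit, V19 against 1A gave 2415 calls (1590) and the V19 interaction 1030 (254), with a spread estimated from fewer libraries. Without the 3 groups and 1 library that stood apart, a setting chosen after seeing the data, Ezh2 knockout at 96 h gave 2989 calls (1992) and the V19 interaction 601. Leaving out 1 library at a time gave 1180 to 1712 calls for Ezh2 knockout at 96 h, where 1A wild type replicate 1 (1180) and Ezh2 knockout replicate 3 (1325) moved the count by over 1.5 times. For the other 16 counts the range stayed within that factor.

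The correlation of the V19 and 1A responses (0.818) was 0.437 without a filter, 0.857 with the stricter one and 0.808 in the RUV-normalized values. For genes chosen in V19 as higher, 1A wild type (1.27) gave 1.24 without a filter, 1.31 with the stricter one and 1.37 by RUV, Eed knockout (0.71) gave 0.68 with the stricter filter and 0.65 by RUV, and Ezh2 knockout (0.93) gave 0.88 without a filter. For genes chosen as lower, Eed knockout (-0.48) gave -0.49 with RLE, -0.50 with the stricter filter and -0.52 by RUV, and Ezh2 knockout (-1.27) gave -1.23 without a filter and -1.32 by RUV. The filters change which genes are read, and the cause of the RLE and RUV moves was not tested. The medians of both knockouts stayed closer to 0 than those of 1A wild type under all 5 settings. At these depths small changes were recovered least often in simulated data, 58.2% of 1.5-fold changes of the 1A wild-type response at 96 h and 23.9% of 1.5-fold differences of the Eed response, and depth itself was not varied.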

Other observations

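The gene lists in the first 2 paragraphs were set before the data were examined, and the tests on interferon genes and parts of the ERK list were chosen after the result was seen, as were those of gene length, while the test of 4 blocks along chromosome 8 was written before its values. Cell cycle inhibitors rose in 2i in all 4 lines. In 1A wild type 5 of 11 were higher at 12 h and none called lower (median 0.30, adjusted p = 0.018), and at 96 h 6 were higher and 1 lower (median 0.68, adjusted p = 0.020), with Cdkn1a at 1.98 ± 0.08 and Cdkn1b at 0.68 ± 0.10. In V19 at 96 h 7 were higher and 1 lower (median 0.79, adjusted p = 0.031). At 96 h in Eed knockout 4 were higher and none called lower (median 0.40, adjusted p = 0.015, a call that ended at a median of 0.23 in the RUV-normalized values), and in Ezh2 knockout 5 were higher and 1 lower (median 0.47, adjusted p = 0.017), and these counts were the same adjusted over the list alone. The imprinted member Cdkn1c fell in 1A wild type (-1.71 ± 0.13) and rose in Eed knockout (2.43 ± 0.11, or 1.52 in the authors' RUV-normalized values), a difference of 4.14 ± 0.17. Before 2i, 9 of 11 inhibitors were higher without Eed (the same adjusted over the list alone, median 0.89, adjusted p = 0.0060), with Cdkn2a at 1.51 ± 0.20. In the RUV-normalized values this call ended at a median of 0.36, Cdkn2a was at 0.58, and Cdkn1c was at -2.43 where raw counts gave 0.79 ± 0.11.

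Genes of the Polycomb complexes did not move one way in 2i. In 1A wild type at 96 h 6 of 20 PRC1 subunits were higher and 3 lower (median 0.09, adjusted p = 0.38), and 4 of 14 PRC2 subunits were higher and 3 lower (median 0.06, adjusted p = 0.94), with the same counts adjusted over the list alone. The PRC2 cofactors Jarid2 (-1.42 ± 0.12) and Phf19 (-2.99 ± 0.19) fell and Mtf2 rose (0.64 ± 0.07), while the PRC1 genes Bmi1 (1.64 ± 0.14) and Cbx8 (3.21 ± 0.30) rose. Without Eed both were already higher at 0 h, Bmi1 by 2.52 ± 0.13 and Cbx8 by 3.58 ± 0.28 (1.13 and 1.86 in the RUV-normalized values). Mesendoderm genes were higher without Eed at 0 h in 6 of 11 cases with none called lower (6 and 1 adjusted over the list alone, median 1.52, adjusted p = 0.0035), with Foxa2 at 4.43 ± 0.34 (1.71 in those values) and Eomes at 2.69 ± 0.20. Neuroectoderm genes fell in V19 at 96 h in 7 of 16 cases and rose in 1 (the same adjusted over the list alone, adjusted p = 0.024), and their median of -0.56 was -0.26 with 1 member at its bound and -0.27 with the stricter filter. By raw counts the imprinted RNA H19 in Eed knockout was at 1805 ± 118, 2202 ± 209, 3817 ± 251, 5492 ± 175 and 2689 ± 49.3 CPM over the 5 times, and in 1A wild type at 16 ± 1.87, 16.6 ± 2.76, 27.7 ± 1.74, 64.0 ± 12.3 and 22.6 ± 3.09 CPM.

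Genes of chromosome 8 were higher in V19 than in 1A wild type along its whole length. The medians of 4 blocks of 203 neighbouring genes were 0.34, 0.40, 0.44 and 0.42, with 79, 87, 97 and 92 genes called higher. After removal of the median of other genes of the same length the chromosome stood at 0.41, which argues against length bias. A candidate explanation is an extra copy of the whole chromosome in many or all V19 cells, a hypothesis whose test, a lowest block above 0.2, was met with 0.34, although 3 copies in place of 2 in every cell would give 0.58. DNA was not analysed here, and another difference between the lines remains open.

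Interferon-stimulated genes rose in Eed knockout, with 18 of 21 higher and 1 lower at 96 h (median 1.95, adjusted p = 1.1e-07 with an estimated correlation, adjusted over these added tests alone), and their response exceeded that of 1A wild type in 10 cases and fell below it in 2 (median 2.05, adjusted p = 2.3e-06 with an estimated correlation, 1.83 in the RUV-normalized values). With the stricter filter the median of this difference was 1.61 over 19 genes. Rsad2 went from 1.88 ± 0.313 to 41.4 ± 1.77 CPM, while the list had medians of -0.06 in 1A wild type and 0.80 in Ezh2 knockout (adjusted p = 0.46 with an estimated correlation). Fibroblast or feeder cells are argued against, since Col1a1 and Col1a2 together changed by -0.988 CPM while the list gained 360 CPM. Reads shared between paralogs on the list are argued against too, since 16 genes without a close paralog there had a median difference of 1.85. Reads shared with paralogs outside the list were not examined. Of the 15 tested fibroblast markers, of which 0 are on the interferon list and 6 were at a mean of at least 5 CPM in 1A wild type at 0 h, 5 rose and 3 fell in Eed knockout over 96 h (median 0.33), and 10 were higher and 2 lower than in 1A wild type at 96 h (median 1.46). The genes were chosen after Isg15 and Oasl2 were seen to rise, so the median of 2.05 cannot decide whether Eed knockout cells mount an interferon-type response in 2i, which stays a hypothesis.

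Feedback targets of ERK rose between 48 and 96 h, but only in part. At 96 h the whole list of ERK targets was still below 0 h. Its medians were -1.13 in 1A wild type, -1.25 in V19, -0.70 in Eed knockout and -1.40 in Ezh2 knockout. Of 12 feedback regulators and ETS factors, 9 rose in 1A wild type (median 0.73) and 10 in V19 (0.80). In Eed knockout 10 rose with 1 lower (0.87), and in Ezh2 knockout 9 rose (0.61). Spry4 was at 3.35 ± 0.22 and Etv4 at 2.58 ± 0.16 in 1A wild type. The V19 change starts from uneven 48 h libraries, with replicates 2 and 3 at root mean square deviations of 0.357 and 0.267 log2 units. The length-matched median of these 12 genes in 1A wild type was 0.62, which argues against length bias in that line. The other lines were not length-matched. If inhibitor activity had been lost before the 96 h harvest, immediate early genes could have risen too, but the set of 5 was called higher in Ezh2 knockout (2 higher, 0 lower, adjusted p = 0.048 with an estimated correlation) and not called in the other 3 lines, with medians of -0.016, -0.06, -0.10 and 0.42 in 1A wild type, V19, Eed knockout and Ezh2 knockout, where Myc was at 1.27 ± 0.15, 2.07 ± 0.20, -1.63 ± 0.11 and 2.43 ± 0.15. Loss of the inhibitor and an adaptation of the cells therefore cannot be told apart, and no library without a daily change of inhibitor was analysed here.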
